A study of Mus musculus with 6 samples.

How the data were processed

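RNA was measured in C2C12 cells, a mouse myoblast line that fuses into multinucleated myotubes in low-serum medium. Per the labels' protocols, the myoblasts were grown in medium with 10% fetal bovine serum and given a lentivirus with a short hairpin RNA, either against Gaa (shGAA) or of scrambled sequence (shScrambled). Cells carrying the virus were selected with puromycin and differentiated in medium with 2% horse serum and 4.5 g/l glucose. Libraries were made from 1 ug of total RNA with Illumina protocols. The groups hold 3 libraries each. The labels do not say how many hairpin sequences were used, or whether the 3 libraries of a group came from separate infections, cultures or wells. The p-values therefore measure only the spread between these libraries, which may be technical. The sample titles also carry the word Fed in both groups, which the labels do not explain.

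The authors deposited 1 table of raw read counts per gene symbol, with 1 column of whole-number counts per library. The submitters' processing notes name the mouse build mm10, HISAT2 2.1.0 (a spliced aligner), Subread (a suite that includes a read counter), FastQC and edgeR. The gene annotation, the treatment of reads that map to several genes and the use of strand in counting are not given in the sources used here. Reads of near-identical genes, or of genes that overlap on opposite strands, can therefore have been counted for the wrong gene or left out. The table lists 24421 symbols, of which 8068 have no count in any library. It contains 0 mitochondrially encoded symbols, so the list of mitochondrially encoded transcripts fixed in advance was not analysed here.

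All tests started from these counts. Genes were kept by filterByExpr with the group as its argument, which left 11801 tested genes holding 99.9% of the counts of each library. Libraries were scaled by TMM, with factors between 0.979 and 1.02. The test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3, robust fit, group as the only term), with Benjamini-Hochberg adjustment over all tested genes. A gene was called higher or lower in shGAA at an adjusted p under 0.05. Fold changes are log2 of shGAA over shScrambled, followed by their standard error (SE), the size of the fitted coefficient divided by the square root of its F statistic. Expression is given in CPM, the count divided by the TMM-scaled library size and put on a common scale, as mean ± SD over 3 libraries.

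Before the data were examined, 23 gene lists were fixed from textbook knowledge of muscle, glycogen, lysosomes, stress responses and other cell types a culture could hold. They were glycogen metabolism and glycophagy, glucose uptake and glycolysis, lysosome, autophagy, the tricarboxylic acid cycle with nuclear-encoded subunits of oxidative phosphorylation, mitochondrially encoded transcripts, fatty acid uptake and oxidation, cholesterol synthesis, fatty acid synthesis, sarcomere, myogenic regulators, undifferentiated myoblast markers, cell cycle, interferon response, integrated stress and unfolded protein response, p53 targets, NRF2 targets, extracellular matrix, insulin signalling, and markers of adipocytes, osteoblasts and chondrocytes, leukocytes and endothelium. The 19 lists with at least 5 tested members were tested with camera (limma 3.58.1), which compares a list with the other tested genes, at a preset inter-gene correlation of 0.01 and with adjustment over the 19 lists. The same test with a correlation estimated from these 6 libraries, and fry, which tests whether a list's genes move one way on balance, were run as alternatives. Members were also counted with the adjusted p computed over the list alone.

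The genes named were chosen by a rule set in advance. It took Gaa and a fixed set of genes of glycogen handling, lysosomes and their regulators (among them Gys1, Gbe1, Pygm, Stbd1, Gabarapl1, Lamp2, Tfeb and Ppargc1a) whatever their test. It then took the 12 genes with the largest rise and the 12 with the largest fall among genes with an adjusted p under 0.05, a mean of at least 5 CPM, no overlap between the groups and no predicted or clone symbol. Last came up to 4 members per list, those with the smallest adjusted p among the called ones. The rule gave 111 genes, some of which are not reported here.

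The code was first tested on simulated counts for 11801 genes with the means, dispersions and library sizes of this comparison, of which 200 were changed. It recovered 77% of genes changed 1.5-fold and 91% of those changed 2-fold, and 4.15% of its calls fell on unchanged genes. A simulated list of 40 genes shifted by 0.3 on the log2 scale gave p = 1.04e-27 in camera with the preset correlation and p = 0.000209 with an estimated one. The simulated genes varied independently of each other, and far fewer were changed than were called in the data. In the data the estimated inter-gene correlation was 0.382 for the cell cycle list and 0.343 for the interferon response list. The simulation therefore does not show how either list test behaves with correlated members.

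Alternatives fixed in advance were other scalings (relative log expression, upper quartile, library size only), no filter on low counts, a filter of 1 CPM in all 6 libraries, a non-robust fit, a minimum fold of 1.2 (glmTreat), DESeq2 1.42.0, limma-voom, the replicate number as a block, and each library left out in turn. A correction for transcript length and GC content, fitted per library on the longest GENCODE M21 transcript of each gene, was added after the data had been seen. Gene positions are from RefSeq on GRCm38.p6, the assembly that mm10 names, and 11781 of the 11801 tested symbols matched a RefSeq symbol or synonym. The share of each named gene's 50-base stretches found in transcripts of other genes, and the share of its exonic bases overlapped by other genes, were computed from GENCODE M21. The authors' own annotation may differ from both.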

Results

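Gene expression was profiled by RNA sequencing in C2C12 mouse cells put through myotube differentiation. They carried a hairpin against Gaa (shGAA, n = 3 libraries) or a scrambled hairpin (shScrambled, n = 3 libraries). How far the cells had differentiated was not measured. In shScrambled the 62 sarcomere and contraction genes summed to 7150 to 7802 CPM and the 46 cell cycle genes to 4577 to 5062 CPM. Cell cycle transcripts were therefore still present in the controls. Gaa encodes lysosomal acid alpha-glucosidase, the enzyme that releases glucose from glycogen inside lysosomes. The series concerns glycophagy, the delivery of glycogen to lysosomes by autophagy. The comparison asks which transcripts differ in these cultures when the RNA of this enzyme is reduced. The libraries held 9686367, 9224038 and 10430270 counts in shGAA 1 to 3 and 9918142, 9515046 and 9475245 in shScrambled 1 to 3. Between 14361 and 14489 symbols had at least 1 count per library, and the 10 most abundant genes held 4.53% to 4.71% of the counts. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.95 to 2.54 in shGAA and 2.25 between shScrambled 2 and 3. The library shScrambled 1 stood apart from the others of its group, at 5.87 and 5.31. The first principal component held 66.4% of the variance and separated the groups, and the second held 13.4% and separated shScrambled 1 from the others.

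Gaa itself was lower in all 3 shGAA libraries than in any shScrambled library. It had 469, 445 and 552 counts in shGAA 1 to 3 and 1033, 1158 and 1119 in shScrambled 1 to 3, or 49.1 ± 2.43 against 117 ± 9.43 CPM. The log2 fold change was -1.25 ± 0.07 (SE, n = 3 per group, adjusted p = 1.09e-09), a 2.37-fold reduction, so that 42.1% of the control transcript level was left. Gaa (Entrez 14387) lies on chromosome 11 at 119267963 to 119285458 on GRCm38.p6. None of its 50-base stretches occur in transcripts of other genes, a share of 0%, and no exon of another annotated gene overlaps its own. The hairpin's target position within the transcript was not analysed here. The amount and activity of the enzyme were not measured in these data.

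Cultures with the Gaa hairpin had more RNA from most interferon-stimulated and p53 target genes tested, and from 34 of 65 lysosomal genes. They had less RNA from most cell cycle, sarcomere and myogenic genes, and from 14 of 36 glycolytic genes. These list calls are those of camera with a preset correlation, and with an estimated correlation none of them held, with an adjusted p = 0.514 for the lysosome list and 0.205 to 0.210 for the others. Of 11801 tested genes, 2182 were higher in shGAA and 2330 were lower, together 38.2%, and 7289 did not pass the test. Most changes were small. The median absolute log2 fold change of the called genes was 0.37, and 180 genes rose and 214 fell at least 2-fold. Higher genes made up 48.4% of the calls. With library size as the only scaling they made up 60.0%, from 2809 higher and 1872 lower genes. Precision followed expression, with a median SE of 0.05 in genes of 100 CPM or more and 0.28 in genes of 1 to 5 CPM.

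**Figure D1:**
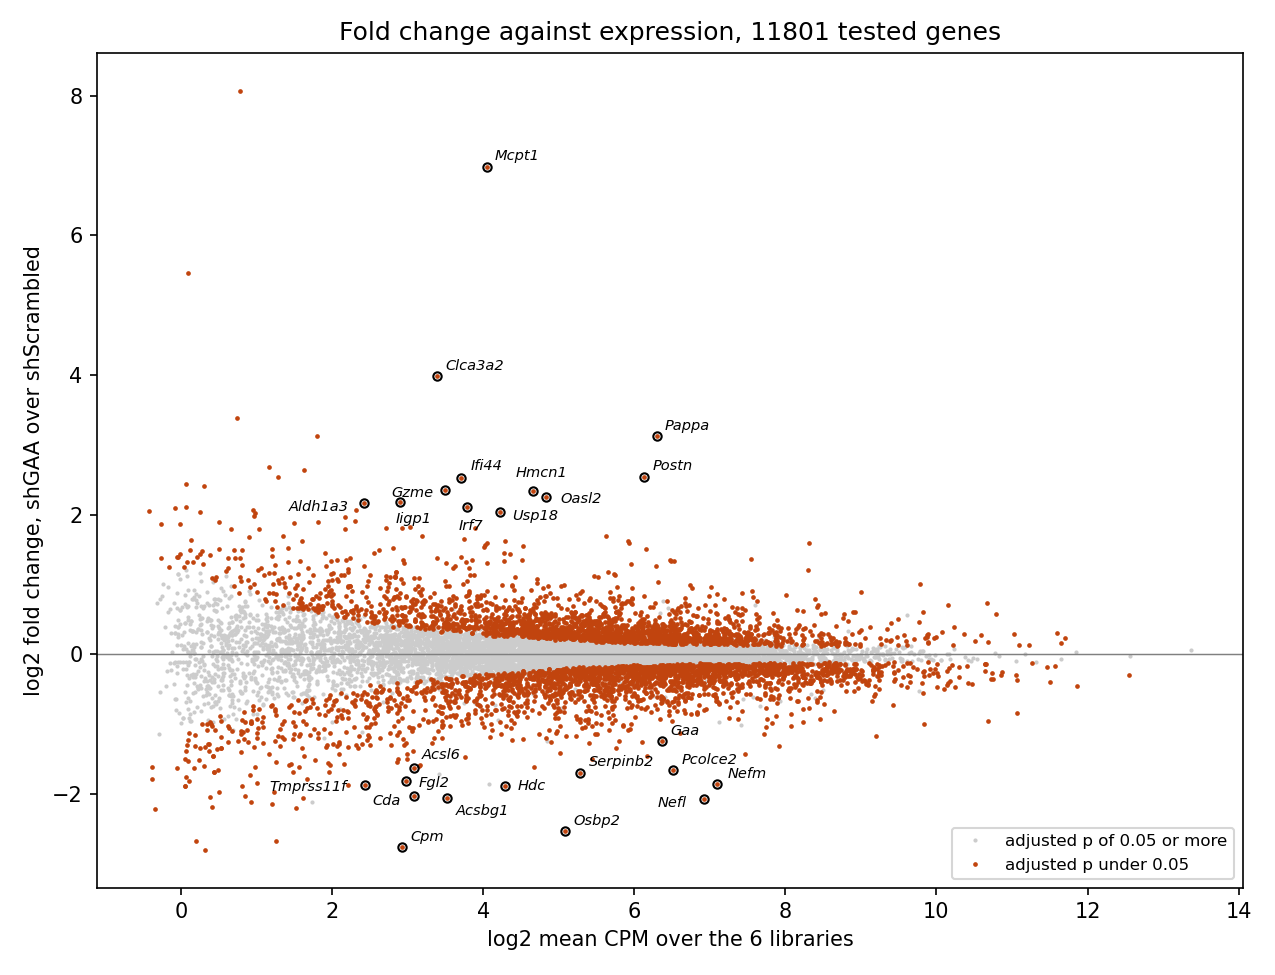
Log2 fold change of shGAA over shScrambled (vertical axis) against log2 mean CPM over the 6 libraries (horizontal axis) for 11801 tested genes, with genes of adjusted p under 0.05 in orange and the others in grey. Circles mark Gaa, at -1.25, and the genes named for the largest rises and falls, from Mcpt1 at 6.99 to Cpm at -2.77.

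The largest rise among the named genes was that of Mcpt1, a mast cell protease gene on chromosome 14, at 32.8 ± 2.69 CPM in shGAA against 0.245 ± 0.12 in shScrambled. It had 981 counts over the 3 shGAA libraries and 7 over the 3 shScrambled libraries, a ratio of 134 with a 95% counting interval of 64.6 to 333. Such intervals cover counting error only. Clca3a2, of a family of chloride channel accessory proteins, followed with 586 against 35 counts, a ratio of 16.0 (11.3 to 23.1), and shares 24.0% of its 50-base stretches with Clca3a1. Pappa, a metalloproteinase that cleaves insulin-like growth factor binding proteins, rose by 3.12 ± 0.13 on the log2 scale (adjusted p = 1.11e-07), from 16.2 to 141 CPM. The matricellular protein gene Postn rose by 2.54 ± 0.11 (adjusted p = 4.67e-08) and Hmcn1, which encodes an extracellular hemicentin, by 2.33 ± 0.11. Gzme, a granzyme gene in the same stretch of chromosome 14 as Mcpt1, rose by 2.35 ± 0.16 and shares 12.7% of its 50-base stretches with Gzmd. Aldh1a3, which makes retinoic acid, rose by 2.17 ± 0.22. The other 5 genes of this group, Ifi44, Oasl2, Iigp1, Irf7 and Usp18, are interferon-induced genes, with log2 rises between 2.04 and 2.52.

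Among the largest falls were those of the neurofilament genes Nefl and Nefm. Nefl fell by 2.08 ± 0.08 on the log2 scale, from 195 to 46.2 CPM (adjusted p = 1.39e-09), and Nefm fell by 1.86 ± 0.12, from 215 to 58.9 CPM (adjusted p = 7.29e-06). In GENCODE M21 their exons overlap on opposite strands over 32.8% of Nefl, although their RefSeq positions do not overlap. Their reads may therefore not be fully separate, depending on the annotation used for counting. Osbp2, an oxysterol-binding protein gene, changed by -2.54 ± 0.10, and the acyl-CoA synthetase genes Acsbg1 and Acsl6 by -2.07 ± 0.16 and -1.63 ± 0.15. Hdc, which makes histamine, changed by -1.89 ± 0.19, the cytidine deaminase gene Cda by -2.04 ± 0.23 and the prothrombinase gene Fgl2 by -1.82 ± 0.23. The others were Cpm (carboxypeptidase M, -2.77 ± 0.47), the serine protease gene Tmprss11f (-1.87 ± 0.19), the protease inhibitor gene Serpinb2 (-1.70 ± 0.12) and the procollagen processing enhancer gene Pcolce2 (-1.67 ± 0.06). Cpm was the least even of these, at 13.3 ± 6.54 CPM in shScrambled against 1.94 ± 0.446 in shGAA.

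Genes of glycogen metabolism changed in both directions. Of 24 tested members of the list, 4 rose, 4 fell and 16 did not pass, with the same counts of 4 and 4 adjusted over the list alone. The rises were led by Phka2, a regulatory subunit of phosphorylase kinase (0.50 ± 0.06, adjusted p = 1.19e-05), and Pygb, the brain form of glycogen phosphorylase (0.46 ± 0.07, adjusted p = 8.89e-05). The muscle form of the phosphorylase, Pygm, was low in both groups and fell from 7.63 ± 0.808 to 3.83 ± 0.581 CPM (-0.99 ± 0.18, adjusted p = 0.000345). Pgm2, which interconverts glucose phosphates, fell by 0.41 ± 0.06. Stbd1, which encodes a glycogen-binding protein assigned to glycophagy, fell by 0.28 ± 0.07 (adjusted p = 0.00263), while its partner gene Gabarapl1 was at 0.05 ± 0.06 (adjusted p = 0.520). Glycogen synthase (Gys1, 0.09 ± 0.06, adjusted p = 0.295) and the branching enzyme (Gbe1, -0.03 ± 0.10, adjusted p = 0.855) did not pass the test. As a whole the list did not stand apart from other genes, with a median log2 fold change of 0.05 and a camera adjusted p of 0.615.

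**Figure D2:**
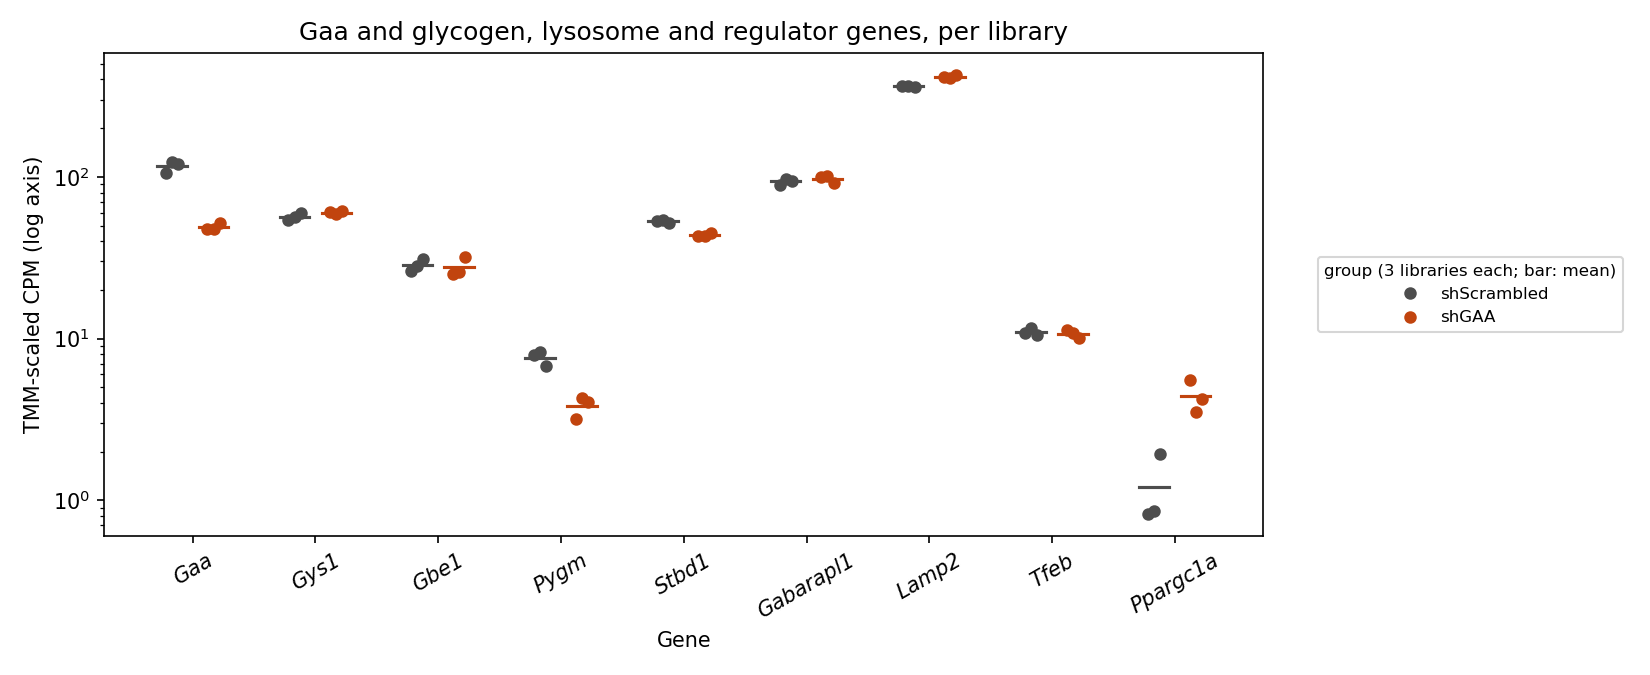
TMM-scaled CPM on a log axis for Gaa and 8 of the genes named whatever their test, with a point per library, 3 shScrambled (grey) and 3 shGAA (orange), and a bar at each group's mean. Gaa, Pygm and Stbd1 sit lower in every shGAA library and Lamp2 and Ppargc1a sit higher, while the groups overlap for Gys1, Gbe1, Gabarapl1 and Tfeb.

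More lysosomal genes rose than fell, but the summed CPM of the list overlapped between the groups. It was 12807 to 13461 in shGAA and 12387 to 13049 in shScrambled. Of 65 tested, 34 rose, 7 fell and 24 did not pass (37 and 8 adjusted over the list alone), with a median of 0.20. The sulfatase gene Arsb, whose product degrades glycosaminoglycans, rose by 0.73 ± 0.07 (adjusted p = 6.07e-07). The major lysosomal membrane proteins moved apart, since Lamp2 rose by 0.20 ± 0.04 (adjusted p = 0.00129) and Lamp1 fell by 0.40 ± 0.05 (adjusted p = 4.43e-06). Npc1, a lysosomal cholesterol exporter, fell by 0.47 ± 0.06. In camera the adjusted p was 0.000138, against an adjusted p = 0.514 with an estimated correlation. The median lysosomal gene in shScrambled 1 lay 0.08 below the mean of the other shScrambled libraries, and the median autophagy gene 0.09 below. Autophagy genes showed 20 rises, 3 falls and 31 without a call among 54, the same 20 and 3 adjusted over the list alone, with a median of 0.08. Calcoco1, a receptor for selective autophagy, rose by 0.68 ± 0.06, Rb1cc1, part of the initiating kinase complex, by 0.52 ± 0.06, Flcn (folliculin) by 0.67 ± 0.08 and Atg12 by 0.37 ± 0.06. Their camera adjusted p was 0.00775, and adjusted p = 0.515 with an estimated correlation. Tfeb, a transcription factor for lysosomal and autophagy genes, was at -0.04 ± 0.13 (adjusted p = 0.846). The 3 falls among autophagy genes became 7 without shScrambled 1, and 1 without shGAA 3, shScrambled 2 or shScrambled 3 and with library size as the only scaling.

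Among genes of glucose uptake and glycolysis more fell than rose. Of 36 tested, 2 rose, 14 fell and 20 did not pass (2 and 15 adjusted over the list alone), with a median of -0.17. Muscle enolase Eno3 fell by 0.77 ± 0.05 (adjusted p = 2.87e-09), the glucose transporter gene Slc2a1 by 0.67 ± 0.06 (adjusted p = 1.80e-07), Ldha by 0.43 ± 0.05 and Pgk1 by 0.44 ± 0.05. Pgk1 shares 67.9% of its 50-base stretches with Pgk1-rs7. The camera adjusted p was 0.000486, and adjusted p = 0.205 with an estimated correlation. In shScrambled 1 the median member was 0.14 below the mean of the other shScrambled libraries. The count of 2 rises was 1 without shGAA 2 or shGAA 3 and in DESeq2. Gapdh, a gene of this list chosen after its values were seen, was erratic within both groups. It had 68, 77 and 370 counts in shGAA 1 to 3 and 112, 924 and 107 in shScrambled 1 to 3, and shares 27.2% of its stretches with Gm7336. Eno1, also on the list, shares 70.5% of its stretches with Eno1b. Reads of such genes may have been left out, so their counts may not reflect their RNA.

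Most nuclear-encoded genes of mitochondrial energy metabolism did not pass the test. Of 92 tested members of the tricarboxylic acid cycle and the oxidative phosphorylation complexes, 3 rose, 28 fell and 61 did not pass (3 and 26 adjusted over the list alone), with a median of -0.11. The muscle cytochrome oxidase subunit gene Cox6a2 fell by 1.80 ± 0.24 from a low level of 4.93 CPM, Atp5e by 0.42 ± 0.07, Cox5b by 0.34 ± 0.06 and Mdh2 by 0.22 ± 0.05. Cox5b shares 25.9% of its stretches with Gm11273. The camera adjusted p was 0.00775, and adjusted p = 0.635 with an estimated correlation. The call ended without shGAA 3 (adjusted p = 0.0533, 12 lower members) and with the length and GC correction (adjusted p = 0.499, 7 higher and 12 lower members), and 17 and 16 members were lower without shGAA 1 and without shScrambled 2. Other settings gave 5 higher and 15 lower members with library size as the only scaling and 17 lower with DESeq2, and the 3 higher members were 1 without shGAA 2. Ppargc1a, a coactivator of mitochondrial genes, rose by 1.88 ± 0.31 (adjusted p = 0.000158), a 3.67-fold rise to 4.42 CPM.

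Lipid genes went both ways. Among 37 tested genes of fatty acid uptake, storage and oxidation, 6 rose, 11 fell and 20 did not pass, the same adjusted over the list alone. Besides the rise of Ppargc1a, the triglyceride synthesis gene Dgat2 fell by 1.03 ± 0.17, the lipid droplet coat gene Plin2 by 0.32 ± 0.05 and Cpt1a, the carnitine transferase for mitochondrial fatty acid entry, by 0.36 ± 0.06. The list had a median of -0.02, a mean of 0.00 and a camera adjusted p of 0.615 in the lower direction. Of 16 fatty acid synthesis genes, 2 rose, 5 fell and 9 did not pass (2 and 6 adjusted over the list alone), with a median of -0.12. The desaturase gene Scd2 was the main change, falling by 0.96 ± 0.06 from 2174 to 1114 CPM (adjusted p = 3.24e-07). Me1, which supplies NADPH and shares 24.3% of its stretches with Gm7049, fell by 0.37 ± 0.06, and Lpin1 rose by 0.63 ± 0.12. Scd1, at -0.15 ± 0.04 (adjusted p = 0.0138), lost its call with library size as the only scaling (adjusted p = 0.0634) and without shGAA 2, shGAA 3 or shScrambled 2 (0.0550, 0.0720 and 0.0805). The fatty acid synthesis list did not pass (camera adjusted p = 0.0689, and adjusted p = 0.515 with an estimated correlation). It passed without shGAA 1 (adjusted p = 0.0402), without shScrambled 1 (adjusted p = 0.0170) and under the length and GC correction and fry. Its 2 rises were 1 without shGAA 1, shGAA 2, shScrambled 1 or shScrambled 3. They were also 1 with the non-robust fit, the replicate block, the length and GC correction, limma-voom and DESeq2. Its 5 falls were 2 without shGAA 2 or shGAA 3, 3 without shScrambled 2 or with library size as the only scaling, and 8 without shScrambled 1. Cholesterol synthesis genes showed 6 rises, 5 falls and 14 without a call among 25, the same adjusted over the list alone. Mvd (0.51 ± 0.08), Fdft1 (0.32 ± 0.06) and Hmgcs1 (0.30 ± 0.06) rose and Acat2, which shares 45.9% of its stretches with Acat3, fell by 0.46 ± 0.08. Their median was -0.04 and their mean 0.03, with a camera adjusted p of 0.865 in the higher direction.

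Genes of the contractile apparatus fell together. Of 51 tested sarcomere and contraction genes, 32 fell, 2 rose and 17 did not pass (33 and 3 adjusted over the list alone), with a median of -0.57 and 42 members below 0. The fast-fibre actinin gene Actn3 fell by 1.14 ± 0.05, from 289 to 131 CPM (adjusted p = 1.17e-10), the calcium channel subunit gene Cacng1 by 0.57 ± 0.05 and Tpm3, a tropomyosin gene sharing 17.0% of its stretches with Tpm3-rs7, by 0.43 ± 0.05. Trdn (triadin), of the sarcoplasmic reticulum, rose by 0.81 ± 0.11. For the list, camera gave an adjusted p of 2.57e-09, and adjusted p = 0.210 with an estimated correlation. The 2 rises were 5 with library size as the only scaling and 4 with no filter on low counts. In shScrambled 1 the median sarcomere gene was 0.18 above the mean of the other shScrambled libraries, and the median myogenic gene 0.05 above. Myogenic regulators and fusion genes had 16 falls, 5 rises and 6 without a call among 27 (16 and 6 adjusted over the list alone), with a median of -0.30 and a camera adjusted p of 0.000138, and adjusted p = 0.205 with an estimated correlation. The falls were led by subunits of the muscle acetylcholine receptor, Chrnd (-1.28 ± 0.08, adjusted p = 6.66e-09), Chrng (-1.14 ± 0.08, adjusted p = 1.85e-08) and Chrna1 (-0.60 ± 0.05), followed by the membrane fusion gene Myof (-0.44 ± 0.04). Markers of undifferentiated myoblasts moved apart. Of 11 tested, 4 rose, 3 fell and 4 did not pass (4 and 4 adjusted over the list alone), with Heyl (1.14 ± 0.12) and Id3 (0.75 ± 0.08) higher and Sdc4 (-1.03 ± 0.06) and Notch1 (-0.84 ± 0.07) lower. This list had a median of 0.10 and a mean of 0.07, and camera gave the lower direction with an adjusted p of 0.996.

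All 46 tested cell cycle genes had a fold change below 0. Of these 36 fell and 10 did not pass, the same adjusted over the list alone, with a median of -0.34. The mitotic genes Kif20a (-0.93 ± 0.05, adjusted p = 1.79e-09), Cdc20 (-0.85 ± 0.05), Prc1 (-0.82 ± 0.06) and Ube2c (-0.81 ± 0.06) led. Kif20a and Ube2c overlap Cdc23 and Tnnc2 on the opposite strand over 29.3% and 22.8% of their exonic bases. The list test gave an adjusted p of 1.26e-17, and adjusted p = 0.205 with an estimated correlation. The median cell cycle gene in shScrambled 1 was 0.12 above the mean of the other shScrambled libraries, and the median p53 target 0.10 below. Targets of p53 rose, with 15 of 24 higher, 0 lower and 9 without a call, the same adjusted over the list alone, and a median of 0.28. Trp53inp1, a stress-induced gene, rose by 1.34 ± 0.07 (adjusted p = 1.66e-09), Perp by 2.07 ± 0.20 from 1.90 CPM, the kinase gene Plk2 by 0.63 ± 0.07 and the cell cycle inhibitor gene Cdkn1a by 0.36 ± 0.04, from 568 to 728 CPM. The camera adjusted p was 4.44e-07, and adjusted p = 0.205 with an estimated correlation. Without shScrambled 1, 1 member was lower.

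The interferon response list changed most. Of 43 tested genes, 35 rose, 1 fell and 7 did not pass (36 and 1 adjusted over the list alone), with a median of 1.24. The guanylate-binding protein gene Gbp2 rose by 1.45 ± 0.12, from 10.4 to 28.3 CPM (adjusted p = 1.38e-07), the double-stranded RNA sensor gene Ifih1 by 1.43 ± 0.12 and Xaf1 by 0.80 ± 0.07. The gene that fell was Ifi27 (-0.30 ± 0.07), chosen after its values were seen, and 2 genes fell without shScrambled 2. Camera gave the list an adjusted p of 8.17e-29, and adjusted p = 0.205 with an estimated correlation. These genes also varied among the control libraries, with a median difference of -0.50 between shScrambled 2 and shScrambled 3 and of 0.26 between shScrambled 1 and the others. Genes of the integrated stress and unfolded protein responses had 20 rises, 7 falls and 20 without a call among 47 (20 and 8 adjusted over the list alone). Ddit3 (0.66 ± 0.08), the asparagine synthetase gene Asns (0.57 ± 0.08) and the folate enzyme gene Aldh1l2 (0.56 ± 0.08) rose, and the serine synthesis gene Psat1 fell by 0.47 ± 0.05. The list had a median of 0.00 and a mean of 0.14 and did not pass (camera adjusted p = 0.0607, and adjusted p = 0.635 with an estimated correlation). It passed without shScrambled 1 (adjusted p = 0.00492), without shGAA 3 (adjusted p = 0.0403) and in several other settings, and its 7 falls were 4 without shGAA 2 or with library size as the only scaling.

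Among antioxidant genes and NRF2 targets more fell than rose, with 15 falls, 4 rises and 13 without a call among 32, the same adjusted over the list alone, and a median of -0.16. Thioredoxin (Txn1) fell by 0.58 ± 0.05 (adjusted p = 1.38e-07), ferritin heavy chain (Fth1) by 0.50 ± 0.04, Prdx1 by 0.28 ± 0.04 and the glutathione synthetase gene Gss by 0.32 ± 0.06. The camera adjusted p was 0.0103, and adjusted p = 0.205 with an estimated correlation. The falls numbered 9 without shGAA 1, without shScrambled 3 and with library size as the only scaling, and the 4 rises were 2 without shGAA 1 or shGAA 2. Extracellular matrix genes changed widely in both directions, with 15 rises, 19 falls and 15 without a call among 49, the same adjusted over the list alone. Besides Postn, the membrane collagenase gene Mmp14 rose by 0.67 ± 0.05, while Col1a1 fell by 1.10 ± 0.10 and the basement membrane gene Nid1 by 0.56 ± 0.05. The median was 0.03 and the mean -0.05, with a camera adjusted p of 0.782 in the lower direction. Insulin, AMPK and FoxO signalling genes had 14 rises, 9 falls and 21 without a call among 44 (15 and 9 adjusted over the list alone), with a median of 0.08 and a camera adjusted p of 0.615. Tbc1d1, a regulator of glucose transporter traffic, fell by 0.56 ± 0.05 (adjusted p = 3.65e-07), Txnip by 0.45 ± 0.05 and Rptor, of the mTORC1 complex, by 0.41 ± 0.06, and the AMPK subunit gene Prkab2 rose by 0.43 ± 0.07.

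Markers of other cell types were few at this depth. Of the osteoblast and chondrocyte markers 6 were tested, of which 2 fell, Spp1 from 2743 to 1529 CPM (-0.84 ± 0.05, adjusted p = 1.28e-09) and Sox9 (-0.50 ± 0.06), and 4 did not pass, the same adjusted over the list alone. Their median was -0.32 and their camera adjusted p 0.00775, and adjusted p = 0.205 with an estimated correlation. Without a filter on low counts the adjusted p was 0.0664. Too few adipocyte, leukocyte and endothelial markers were tested for a list test, and their counts were the same adjusted over the list alone. Of 3 adipocyte markers, Cebpa fell by 0.68 ± 0.15, Pparg rose by 0.54 ± 0.16 and 1 did not pass. Pparg lost its call without shGAA 1 (adjusted p = 0.0560) or shGAA 2 (adjusted p = 0.0656). Of 2 leukocyte markers, Cd14 fell by 0.60 ± 0.10 and 1 did not pass. Of 3 endothelial markers, Tek rose by 1.32 ± 0.29 from 1.52 CPM and Cdh5, at 0.659 against 1.73 CPM, changed by -1.35 ± 0.46, a call lost without shGAA 1, shGAA 2 or shScrambled 2 (adjusted p = 0.116, 0.0997 and 0.155) and in DESeq2 (0.0801), and 1 did not pass.

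Of the 19 lists tested, 11 passed in camera with the preset correlation, 4 higher and 7 lower. With a correlation estimated from these libraries 0 passed in camera after adjustment, and 3 had an unadjusted p under 0.05. With fry, 12 lists had an adjusted p under 0.05. In the lists for which no shift of shScrambled 1 is given above, its median member differed from the mean of the other shScrambled libraries by -0.24 (adipocyte markers) to 0.19 (undifferentiated myoblast markers).

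**Figure D3:**
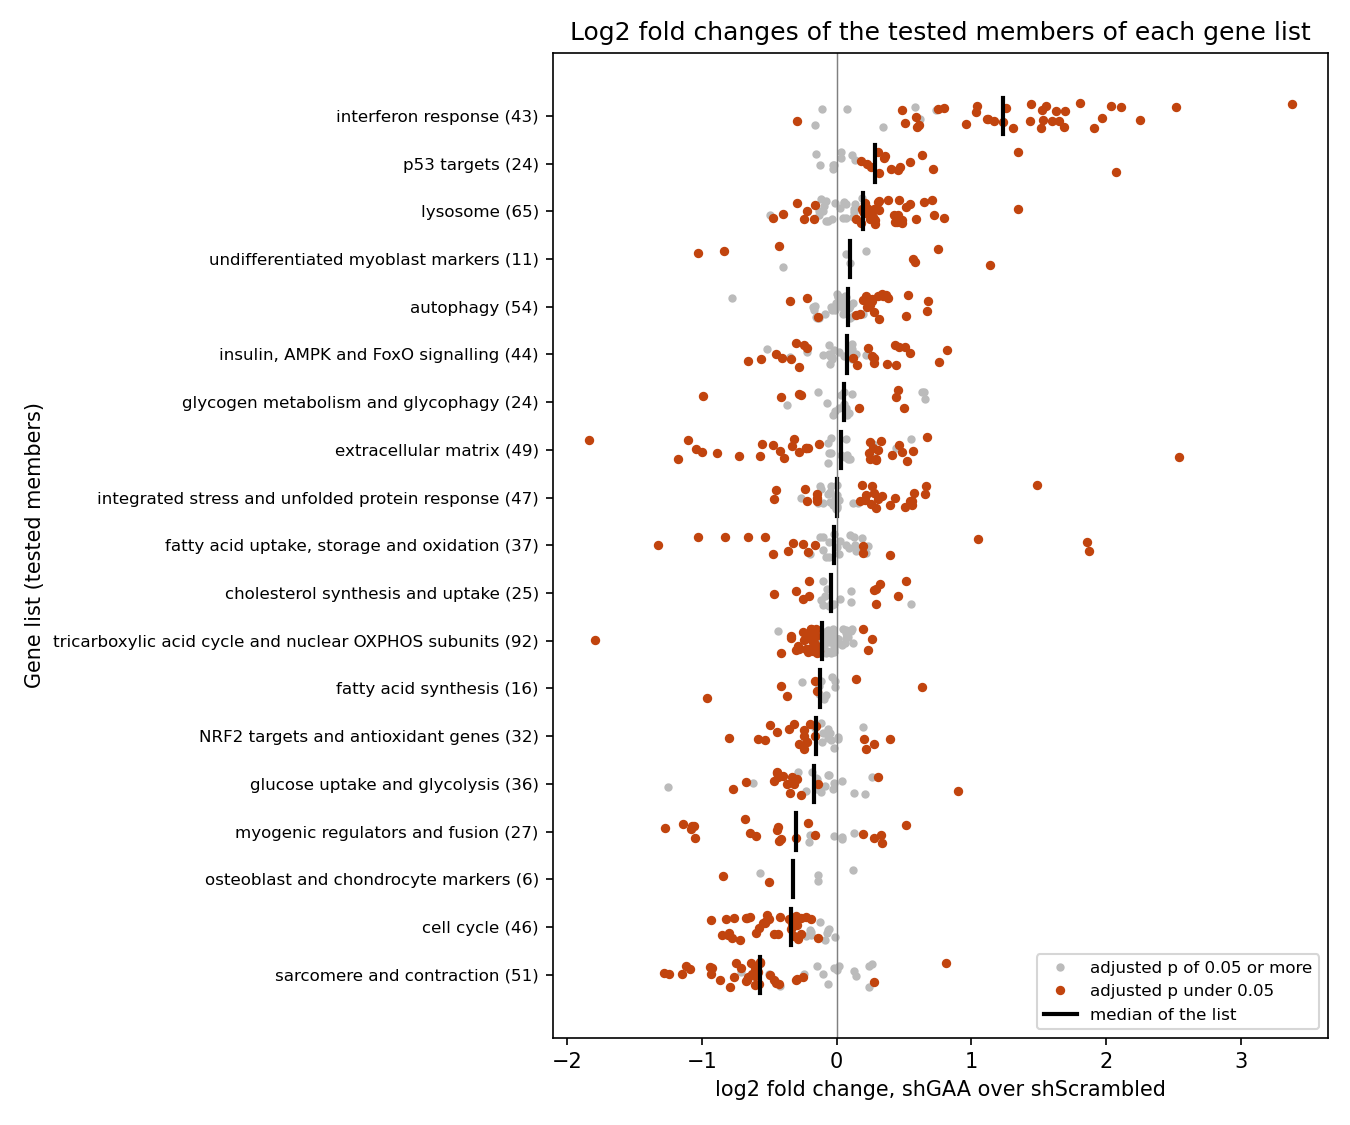
Log2 fold change of shGAA over shScrambled (horizontal axis) for each tested member of the 19 lists with a list test (rows, with the number of tested members), with members of adjusted p under 0.05 in orange, the others in grey and a black bar at each list's median. The interferon response list lies highest, with a median of 1.24, and the sarcomere list lowest, with a median of -0.57, and all 46 cell cycle genes lie below 0.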

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

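The length and GC correction was chosen after the data had been seen, and the other alternatives before. The minimum fold of 1.2 was run for the counts of genes only. Gaa stayed lower in all other fits, with log2 fold changes between -1.31 and -1.20. The counts of higher and lower genes stayed within 1.5 times of 2182 and 2330 in all settings except that minimum fold, which by construction gave 674 and 841. Leaving out 1 library gave 1674 to 2378 higher and 1866 to 2485 lower genes, DESeq2 gave 1563 and 1858 and shared 74.8% of the calls, and all shared calls kept their direction in each fit compared, which leaves out the minimum fold. No list or named gene reversed. With an estimated correlation the adjusted p was 0.205 for glycolysis, myogenic regulators, cell cycle, interferon response, p53 targets, NRF2 targets and osteoblast markers, 0.210 for sarcomere, 0.514 for lysosome, 0.515 for autophagy and 0.635 for the tricarboxylic acid cycle and oxidative phosphorylation. The last list also lost its call with the length and GC correction (0.499), and ranged from 0.00267 to 0.0533 with 1 library left out. The osteoblast list lost its call without a filter (0.0664). The stress response list passed with library size only (0.0339), no filter (0.0355) and the length and GC correction (0.0486), and ranged from 0.00492 to 0.139 with 1 library left out. Fatty acid synthesis passed with the length and GC correction (0.0496) and in fry (0.0269), and ranged from 0.0170 to 0.173. The NRF2 list kept its call with the length and GC correction, at an adjusted p of 0.0496. Across genes the log2 fold change had a Spearman correlation of 0.128 with transcript length and -0.0263 with GC content. The cause of these changes in list calls was not tested further. Of all other values, 2748 kept their side of the threshold or moved little, 51 counts moved by over 1.5 times, 10 gene calls were lost, and in genes under 1 CPM the median SE of 0.45 limits what can be called.

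The values gave no sign that the replicate numbers of the titles pair the samples, which 3 libraries per group cannot exclude. Deviations from the group means of samples with the same number had correlations of -0.04, 0.06 and -0.01 across genes, and not every sample correlated best with its own number. With the replicate block 2037 genes were higher and 2197 lower, and the stress response list passed (adjusted p = 0.0366). The block changed no other list or named gene call.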

Other observations

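The test of reads shared between paralogs, the tests of a single library and of length and GC content, and the splits were set out before their results were seen, and the other tests of this part only after. Most tested genes of a cluster of mast cell protease and granzyme genes on chromosome 14 were higher in shGAA. Between 55941451 and 56132603 on GRCm38.p6, 6 of 7 adjacent tested genes rose. Besides Mcpt1 and Gzme these were Cma1 (2.44, adjusted p = 0.000535), Mcpt8 (0.90, adjusted p = 0.00772), Gzmd (1.80, adjusted p = 0.0141) and Mcpt4, which had 103 counts in shGAA and 0 in shScrambled, at least 32.7-fold higher against a floor of 3 counts over the group. These 4 were chosen after their values were seen. Cma1, Mcpt1, Mcpt4 and Gzmd had means of only 0.317, 0.245, 0 and 0.698 CPM in shScrambled. They passed the filter on low counts only through shGAA, so among tested genes they could only be seen to rise. Genes of the stretch that were low in both groups were not tested, so the share of 6 in 7 does not cover them.

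Another 4 genes outside the named set were chosen after their values were seen. Car9, a carbonic anhydrase induced by hypoxia, fell by 1.59 ± 0.15 on the log2 scale, Stc1 by 1.43 ± 0.29 and Angptl4 by 1.32 ± 0.22, the last pair with higher levels in shScrambled 1 than in the other libraries. The adhesion molecule gene L1cam fell from 64.2 ± 6.38 to 22.7 ± 2.04 CPM (adjusted p = 1.98e-09).

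For the chromosome 14 cluster, RNA from mast cells is argued against by the absence of their abundant transcripts. The summed CPM of Cpa3, Tpsb2, Tpsab1 and Kit differed by -0.0716 between shGAA and shScrambled while Mcpt1 rose by 32.6 CPM, and of 14 markers these cultures themselves express Hdc, which fell, and Gata2. Reads shared with Mcpt1 are argued against too, since 0% of the 50-base stretches of the other risen genes occur in Mcpt1 transcripts, although Gzme shares 12.7% of its own with Gzmd. A change local to the cluster stays open, because the 10 flanking tested genes had a median of 0.108 but went both ways, and Nynrin (0.98, adjusted p = 2.13e-05) and Khnyn (0.34, adjusted p = 0.0124) among them, chosen after their values were seen, rose too. Whether the rise follows from the reduction of Gaa or arose in the selected cell population stays open as well, with 1 shGAA group and 1 shScrambled group.

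For the rise of interferon response genes, a single library is argued against, since at least 31 members were called higher whichever library was left out. Transcript length and GC content are argued against by a median of 1.27 after the correction. RNA from leukocytes is argued against by the absence of their abundant transcripts, since Ptprc and Tyrobp had 0 counts in shGAA and the 16 of 18 markers under 1 CPM in shScrambled, which leaves out Cd14 and Cd68, summed to 0.817 ± 0.302 CPM in shGAA, a difference of -0.547, while the interferon response list rose by 936 CPM. An effect of the hairpin sequence and the reduction of Gaa cannot be told apart. The series holds no separate group with another hairpin against Gaa, and none with a hairpin against an unrelated gene. Both groups were given a lentivirus with a hairpin and selected with puromycin, so the vector as such was shared. The dose of virus in each group was not analysed here. Type I and III interferon genes had 3 counts in all 6 libraries together, which leaves the trigger unseen at this depth.

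For the fall of sarcomere genes together with cell cycle genes, transcript length and GC content are argued against, as the list medians kept at least 89.0% of their size after the correction. The library shScrambled 1, which stands apart, is argued against as the source of these calls, since at least 94.4% as many members were called lower without it. More genes were called in all without that library (4863 against 4512), so the counts alone do not show whether the falls kept their size. The median sarcomere and cell cycle genes in shScrambled 1 lay 0.18 and 0.12 above the mean of the other shScrambled libraries. These shifts are smaller than the list medians of -0.57 and -0.34. A larger share of undifferentiated cells in shGAA stays open, because the 11 tested markers of undifferentiated myoblasts went both ways, with 4 rises, 3 falls and a median of 0.10. Against it, the summed CPM of the list was lower in each shGAA library (1019 to 1046) than in any shScrambled library (1288 to 1338), a sum dominated by Ccnd1 and Sdc4, which fell by 0.43 and 1.03 on the log2 scale, the former chosen after its values were seen. A larger share of dividing undifferentiated cells would raise cell cycle genes, but all 46 tested ones had a fold change below 0, with 36 called lower. These values argue against dividing cells as the added share, but not against undifferentiated cells that had stopped dividing. The reduction of Gaa and an effect of the hairpin itself stay open here as well.

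A lower hypoxia-inducible programme was tested as a hypothesis for the falls of Car9, Stc1 and Angptl4. Of 27 other tested hypoxia-inducible genes 2 rose and 11 fell, with a median of -0.11, and camera gave an unadjusted p of 0.110, which leaves it undecided. The 27 genes leave out Slc2a1, Ldha and Pgk1, which fell and were counted in the glycolysis list. They therefore do not cover all hypoxia-inducible genes that changed. In the glycolysis list 2 rose and 14 fell among 36, but the lists overlap. Both hold Slc16a3, Pdk1 and Pfkfb4, which fell, and Pfkfb3, which did not pass. The falls of the 2 lists are therefore not separate counts. A lower neuronal programme was tested for the falls of Nefl, Nefm and L1cam. Of 10 other tested neuronal genes 4 rose and 3 fell, with a median of 0.06 and an unadjusted camera p of 0.509, which leaves it undecided too.

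Of the 10 ways to split the 6 libraries into 3 and 3, only 1, the real one, gave as many as 4512 called genes, and the highest of the others gave 1 gene. With 10 splits the share cannot fall under 0.05.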
